A study of Mus musculus with 6 samples.

How the data were processed

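Total RNA from whole brown adipose tissue of C57BL/6 mice was sequenced, per the labels, from 3 samples of mice kept on a calorie-rich diet (samples 13, 14 and 15, called untreated) and 3 samples of mice on the same diet with RO5508887 (samples 17, 33 and 35, called treated). The RNA was extracted with Trizol and made into Illumina total RNA libraries, per the labels' protocols. The authors deposited one table per sample with FPKM values (fragments per transcript length and sequencing depth) for 45320 Ensembl gene identifiers, per the file headers. CASAVA 1.7 and the mouse genome build GRCm38 are named in the submitters' processing notes. The aligner, the quantification program and its annotation release were not given in the sources used here. Gene symbols, classes and coordinates came from GENCODE M21 on GRCm38, which held 44395 of the identifiers. The remaining 925 were kept under their identifiers.

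The tables of samples 33 and 35 were identical in all 45320 values, which is less than any sampling noise, and were counted as 1 library, called treated 33/35. The comparison planned for 3 treated and 3 untreated samples was therefore made between 2 treated and 3 untreated libraries. Labels do not say whether the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

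FPKM are not read counts, and the number of reads behind a value was not known. Steps between low values gave the depth of each library relative to untreated 13, which was 0.811 for untreated 14, 0.881 for untreated 15, 1.01 for treated 17 and 0.960 for treated 33/35. No counting interval or detection floor was given. A value of 0 can be a failed estimate, so such genes are described as listed at 0.

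Genes with a mean of at least 1 FPKM over the libraries were tested, 13527 in all. Values were compared on the log2(FPKM + 0.5) scale with limma 3.58.1 in R 4.3.3, by empirical Bayes moderation with a variance trend (residual df of the fit 3). Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are differences of group means on this scale, treated minus untreated, and understate the change of low genes. Of 32 gene lists, 30 had at least 5 tested members and were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and the rotation test fry were run beside it. Fry asks whether the genes of a list move on balance in one direction, and its mixed form whether they change in either direction. Counting and plotting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

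The tests, the lists and the rule for naming genes were chosen before the data were examined. Bace1, Ucp1 and Mir328 were named whatever their p. Up to 10 genes in each direction were to be named if they passed the threshold with no overlap of the groups, without unnamed gene models, pseudogenes, small RNAs, Y-linked genes and Xist. Fewer than 5 passed in either direction, so each was filled to 5 with the genes of smallest p whose groups did not overlap. In each list described, up to 4 members past the threshold adjusted over the list alone were named, or otherwise the 2 of smallest p. The 11 lists described one by one were picked after their values were seen, and the other tested lists are summarised. Ckm and Atp2a1 entered in that way. App, Fos, Myh4, Myh7, Cidea, Adipoq, Dio2, other mast cell and white fat genes, and the 6 genes past the threshold were named after their values were seen.

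The gene test was checked on simulated data with the spread of all 5 libraries, on 13283 genes. It recovered 7.35% of genes changed by 1 on the log2 scale, 40% of those changed by 2 and 71.2% of those changed by 4, with 5 unchanged genes called. With only the spread of untreated 13 and 15, on 13270 genes, the shares were 85.3%, 93.8% and 98.5%, with 18 unchanged genes called. In the list test on 13273 genes, a list of 20 genes shifted by 2 was called with a camera adjusted p of 1.43e-40. Of 30 other lists, 0 were called. The simulated noise was independent between genes, so this check leaves out correlation within lists. The 6 lists called in the real data had estimated correlations from 0.20 to 0.997, so the check says little about false calls among them.

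Alternatives covered the pseudocount, the filter, the scaling, the variance model, sample weights, the most abundant genes, the threshold and each library left out in turn. After the data were seen, 5 more were added: the identical tables counted separately, 2 forms of a skeletal muscle covariate, protein-coding genes alone, and centring on the adipocyte identity list. Alternatives listed in advance for read counts were not run. Acta1, Cox4i1, Rpl13, Mvd, Hbb-b1 and Hbb-b2 had no matching identifier and were not analysed here.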

Results

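The data describe brown adipose tissue of C57BL/6 mice that began a calorie-rich diet, high in fat and sugar, at 4 weeks of age and received it for 4 weeks before they were divided into 2 groups. One group stayed on the diet alone (untreated 13, 14 and 15). The other received the diet with RO5508887, an experimental small-molecule inhibitor of the protease BACE1 (treated 17 and treated 33/35). Samples 33 and 35 held identical values and were counted as 1 sample, which leaves 3 untreated and 2 treated libraries. Brown adipose tissue burns fuel to produce heat, mainly through the uncoupling protein UCP1 in its mitochondria. Between 20876 genes (untreated 15) and 21726 genes (treated 33/35) had a value above 0, and 12729 to 13422 reached 1 FPKM. Read totals were unknown. Mitochondrially encoded genes made up 14.6% of the FPKM sum in untreated 14 and 17.4% to 21.2% in the other 4 libraries.

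Skeletal muscle transcripts and brown fat transcripts separated the libraries before any comparison of groups. Ckm, the muscle creatine kinase, measured 2733 FPKM in untreated 14 but 2.25 and 1.46 FPKM in untreated 13 and 15. It measured 1262 FPKM in treated 17 and 531 FPKM in treated 33/35. Myh7, the slow muscle myosin heavy chain, measured 1115 FPKM in untreated 14, 0.588 and 0.453 FPKM in untreated 13 and 15, and 265 and 140 FPKM in the treated libraries. All 28 skeletal muscle markers tested were highest in untreated 14, next in treated 17 and then in treated 33/35. Myh4, a fast muscle myosin left untested by the filter on low values, was listed at 0 in these 3 libraries and at 1.96 and 1.92 FPKM in untreated 13 and 15. Without read counts a listed 0 does not show that the transcript was absent, and the estimate may have failed. Together the markers took 8.10% of the FPKM sum outside mitochondrial genes in untreated 14, 3.33% in treated 17, 1.42% in treated 33/35, and 0.0331% and 0.0319% in untreated 13 and 15. In untreated 13 and 15, 12 of the 28 markers reached 1 FPKM.

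The list of thermogenic brown fat genes ran the other way in its median, which was lowest in untreated 14, but not in every member. Esrrg measured 17.3 FPKM in untreated 14 against 16.1 and 14.7 FPKM in untreated 13 and 15. Ucp1 (chromosome 8, 83290352 to 83298452, GRCm38) measured 227 FPKM in untreated 14 against 1837 and 1912 FPKM in untreated 13 and 15. Cidea, a lipid droplet protein abundant in brown fat, measured 124 FPKM in untreated 14 against 991 and 1066 FPKM. Dio2, which activates thyroid hormone, measured 2.64 FPKM in untreated 14 against 43.8 and 31.4 FPKM. In treated 17 and treated 33/35 it measured 35.2 and 32.7 FPKM, which does not reverse the order of the muscle markers. Adipoq, the adipocyte hormone adiponectin, differed less, with 332 FPKM in untreated 14 against 602 and 476 FPKM. On log2 values of the tested genes, untreated 13 and 15 had a Pearson correlation across genes of 0.966, whereas untreated 14 had 0.759 and 0.750 with them and 0.903 with treated 17. Genes are not independent replicates, and these values describe the libraries only. The first principal component, 69.8% of the variance, placed untreated 14 at 95.6, treated 17 at 33.1, treated 33/35 at 4.27, and untreated 13 and 15 at -64.5 and -68.4.

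**Figure D1:**
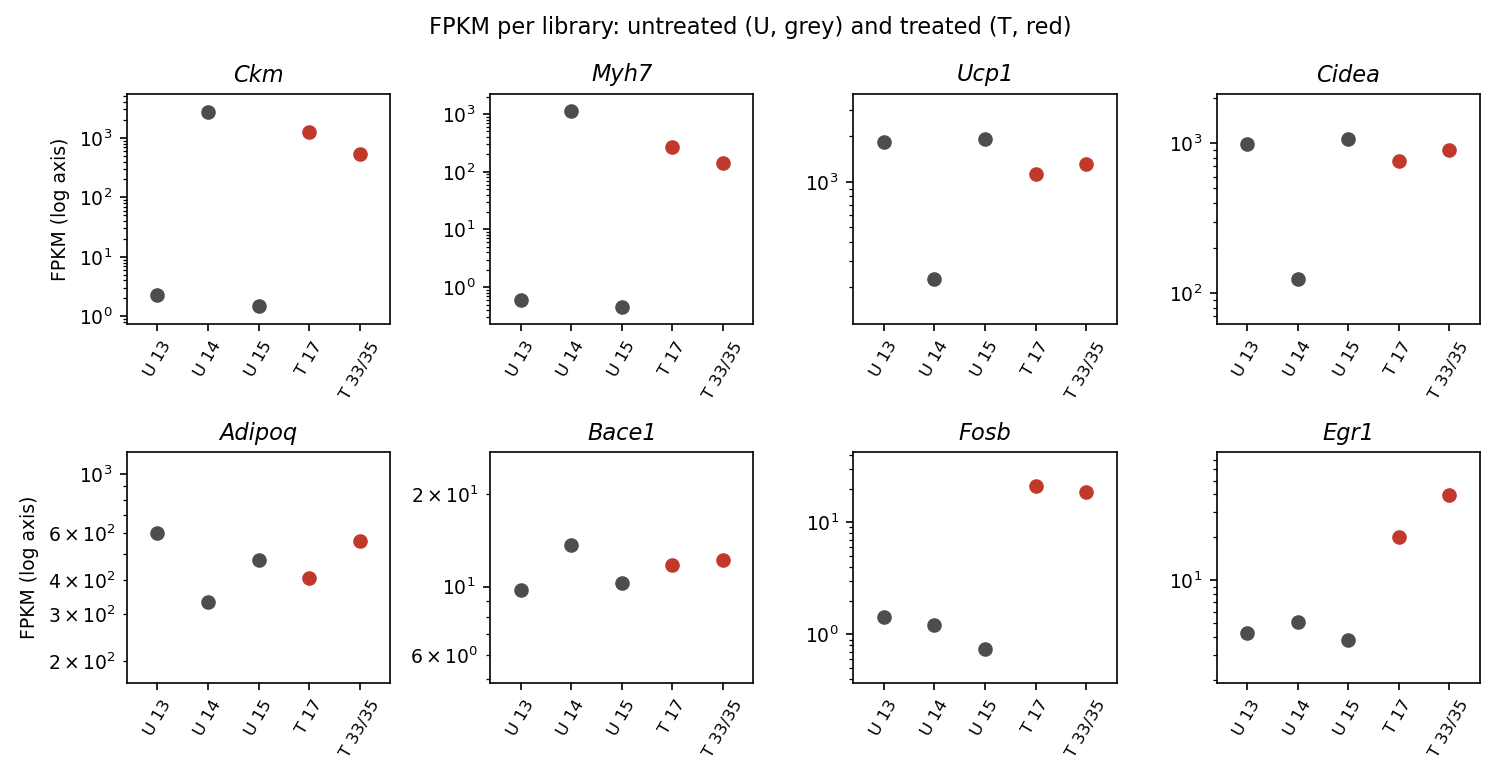
FPKM on a log axis for 8 genes, with 1 point per library (grey, untreated 13, 14 and 15; red, treated 17 and treated 33/35). The muscle genes Ckm and Myh7 are highest in untreated 14, where Ucp1 and Cidea are lowest, and Fosb and Egr1 lie higher in both treated libraries than in the 3 untreated libraries.

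The series asks, by its title and design, how inhibition of BACE1 bears on brown fat under an obesogenic diet, so the drug target and heat-producing genes were compared first. Bace1 (chromosome 9, 45838580 to 45864399) was measured at 11.2 ± 2.13 FPKM (SD, n = 3) without the drug and 12.0 ± 0.372 FPKM (SD, n = 2) with it. Its log2 fold change was 0.10 (SE 0.20, limma adjusted p = 1). The drug acts on the protein, and transcript levels do not measure its activity. Mir328, the microRNA gene named in the title (chromosome 8, 105308364 to 105308460), was listed at 0 in all 5 libraries. The libraries hold total RNA and were not described as small RNA libraries. Ucp1 was measured at 1326 ± 952 FPKM (SD, n = 3) in the untreated group and 1220 ± 143 FPKM (SD, n = 2) in the treated group, a log2 fold change of 0.39 (SE 1.06, limma adjusted p = 1). The treated values of 1119 and 1321 FPKM lay between untreated 14 and the other untreated libraries. Without untreated 14 the log2 fold change was -0.62 (SE 0.12, limma adjusted p = 0.141). That comparison also sets untreated libraries with few muscle transcripts against treated libraries with more, so drug and muscle content cannot be told apart.

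The secretases and known substrates of BACE1 that were tested were close between the groups. Of the list's 28 members, 17 were tested, and the others, among them Chl1, Sez6 and Nrg1, fell below the filter on low values. Among the 17 tested members, 7 had higher and 10 had lower means on the log2 scale with the drug. Of these members, 0 passed the test, also when adjusted over the list alone. Their median log2 fold change was -0.02, with a mean of 0.03 and a camera adjusted p of 0.604. Aph1a, a subunit of gamma-secretase, had a log2 fold change of 0.43 (SE 0.46) and Adam17, an alpha-secretase, -0.12 (SE 0.15), both with a limma adjusted p of 1. Aph1a was lowest in untreated 14, and without that library its log2 fold change was 0.02, against 0.71 without untreated 15. App, the amyloid precursor, measured 74.5, 92.4 and 68.5 FPKM in the untreated libraries and 78.0 and 79.5 FPKM in the treated ones.

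The thermogenic programme of brown fat did not pass the test in either direction. Of 24 tested members, 20 had higher and 4 lower means on the log2 scale with the drug, and 0 passed over all genes or adjusted over the list alone. The median log2 fold change was 0.24 (camera adjusted p = 0.952). Ppargc1a, a coactivator of mitochondrial biogenesis, was measured at 17.0 ± 2.56 FPKM (SD, n = 3) without and 12.9 ± 0.262 FPKM (SD, n = 2) with the drug, and Esrrg, a nuclear receptor, at 16.1 ± 1.28 and 13.5 ± 0.345 FPKM. Both were lower in each treated library than in each untreated one, with limma adjusted p = 1. The list changed the sign of its median with the libraries and the scaling. Its median was -0.26 without untreated 14, the library with 8.10% muscle marker transcripts, and 0.66 without untreated 15. The camera adjusted p was 1.87e-07 and 0.0426, and 0.708 and 0.832 with an estimated correlation. Leaving out untreated 14 sets untreated libraries with few muscle transcripts against treated libraries with more. Centring on the adipocyte identity list, chosen after the results were seen, gave -0.086 (camera adjusted p = 0.0210, and 0.947 with an estimated correlation). That centring moved the median of all genes to -0.26, so the list still lay above it. Camera compares a list with the other genes, so its p there does not speak for a lower list. The mean log2 value of the muscle markers as a covariate, also chosen afterwards, gave 1.60 (camera adjusted p = 3.85e-07, and 0.400 with an estimated correlation). With the mean log2 covariate 14 members passed over all genes as higher. The summed FPKM of the markers as a covariate, also chosen afterwards, gave a median of only 0.14 and 0 members passed. Its camera adjusted p was 0.202, and 0.987 with an estimated correlation. With sample weights the median was -0.21 (camera adjusted p = 0.000465, and 0.704 with an estimated correlation).

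The lists of energy metabolism and adipocyte genes did not pass the test either, and their medians were lowest in untreated 14. Fatty acid beta-oxidation genes had a median log2 fold change of 0.24 over 24 members (camera adjusted p = 0.311). Acaa2, the last thiolase of that pathway, measured 1290, 366 and 1397 FPKM in untreated 13, 14 and 15 and 1137 and 1298 FPKM with the drug, and Acads had a log2 fold change of 0.41 (SE 0.58). Respiratory chain and ATP synthase genes had a median of 0.09 over 55 members (camera adjusted p = 0.952). Cox8a, a subunit of cytochrome oxidase, had a log2 fold change of 0.52 (SE 0.75). Atp5g1, a subunit of the ATP synthase ring, followed the muscle markers, with 530 FPKM in untreated 14, 191 and 89.8 FPKM in the treated libraries, and 12.5 and 9.08 FPKM in untreated 13 and 15. Adipocyte identity genes had a median of 0.18 over 20 members (camera adjusted p = 0.904). Klf15, a transcription factor, measured 20.8 ± 6.07 FPKM (SD, n = 3) without and 11.8 ± 4.18 FPKM (SD, n = 2) with the drug, and was highest in untreated 14. Cebpa, a regulator of adipocyte differentiation, measured 164 ± 75.3 and 208 ± 57.2 FPKM. No member of these 3 lists passed the test over all genes or adjusted over the list alone. Centring on adipocyte identity gave medians of -0.081, -0.24 and -0.15 for the 3 lists in this order, with camera adjusted p of 0.311, 0.00809 and 0.786. The adjusted p was 0.992 for each with an estimated correlation. All of these medians lay above the median of all genes in that fit, -0.26. That centring subtracts the adipocyte list's own median in each library, so the value of that list was set by it. Without untreated 14 the medians were -0.23 for beta-oxidation, -0.15 for the respiratory chain and -0.16 for adipocyte identity, with camera adjusted p of 6.28e-08, 5.18e-08 and 0.00122. The adjusted p was 0.708 for each of the 3 lists with an estimated correlation. Here too the remaining untreated libraries held few muscle transcripts and the treated ones more. Sample weights also called all 3 lower, at -0.19, -0.12 and -0.14 in the same order (camera adjusted p = 0.000501, 7.72e-05 and 0.00642; adjusted p = 0.704 for each with an estimated correlation). Some settings called these lists higher. Quantile normalization called all 3, with medians of 0.30, 0.14 and 0.27 in the same order (camera adjusted p = 8.04e-05, 1.37e-06 and 0.00294; adjusted p = 0.884 for each with an estimated correlation). Without untreated 15, beta-oxidation was at 0.52 and the respiratory chain at 0.23 (camera adjusted p = 0.000779 and 0.00733; adjusted p = 0.832 for both with an estimated correlation), and without untreated 13 beta-oxidation was at 0.48 (camera adjusted p = 0.0144; adjusted p = 0.970 with an estimated correlation). The mean log2 muscle covariate gave 0.94, 0.38 and 0.71 for beta-oxidation, the respiratory chain and adipocyte identity (camera adjusted p = 1.94e-13, 9.87e-10 and 6.40e-05; adjusted p = 0.400, 0.803 and 0.803 with an estimated correlation). The summed FPKM covariate gave 0.19 for beta-oxidation (camera adjusted p = 0.000211; adjusted p = 0.987 with an estimated correlation).

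**Figure D2:**
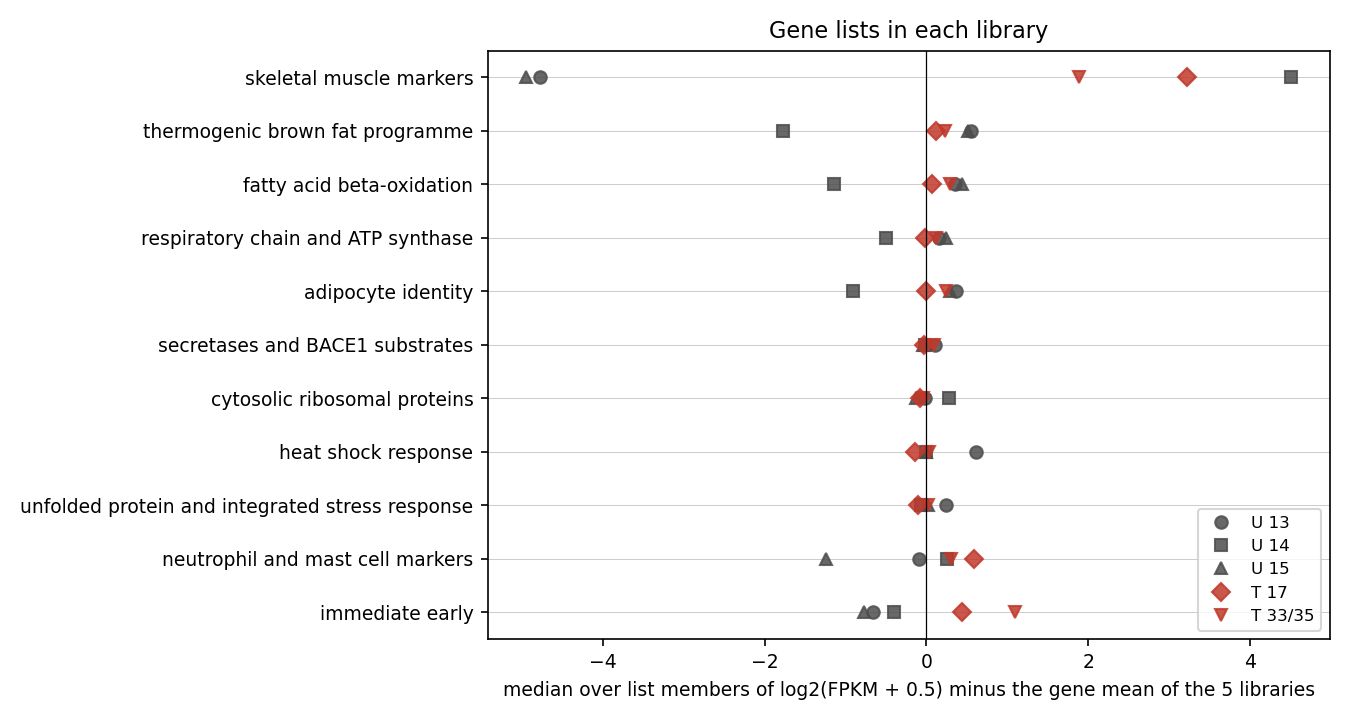
Median over the members of each list of log2(FPKM + 0.5) minus the gene's mean over the 5 libraries, with 1 symbol per library (grey, untreated; red, treated). Skeletal muscle markers lie at 4.51 in untreated 14 and at 3.23 and 1.88 in the treated libraries, against -4.78 and -4.95 in untreated 13 and 15. The thermogenic programme is lowest in untreated 14 at -1.78, and immediate early genes lie at 0.44 and 1.09 in the treated libraries against -0.78 to -0.40 in the untreated ones.

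Immediate early genes had higher means in the treated libraries. These genes are transcribed within minutes of a stimulus, without new protein synthesis. All 21 tested members had higher group means in the treated libraries, with a median log2 fold change of 1.29, and in 15 of them both treated values lay above all 3 untreated values. The list passed the camera test with an adjusted p of 3.05e-38. The adjusted p was 0.282 with an estimated correlation, 0.162 by fry and 0.0289 by the mixed form of fry. Over all genes 0 members passed, and 10 rose when adjusted over the list alone.

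Fosb, a subunit of the AP-1 transcription factor, was measured at 1.13 ± 0.347 FPKM (SD, n = 3) without and 19.9 ± 1.67 FPKM (SD, n = 2) with the drug. Its log2 fold change was 3.67 (SE 0.24), with a limma adjusted p of 0.0665 over all genes and 0.000723 over the list alone. Egr1, a zinc finger transcription factor, was measured at 4.38 ± 0.635 and 29.9 ± 13.6 FPKM, a log2 fold change of 2.57 (SE 0.33, limma adjusted p = 0.777; 0.00482 over the list alone). Klf2, which responds to blood flow in endothelium, was measured at 12.1 ± 1.71 and 41.4 ± 7.13 FPKM, a log2 fold change of 1.73 (SE 0.20, limma adjusted p = 0.579; 0.00482 over the list alone). Egr3 was measured at 0.414 ± 0.113 and 3.53 ± 1.35 FPKM, a log2 fold change of 2.10 (SE 0.32, limma adjusted p = 1; 0.00670 over the list alone). Fos measured 0.627, 11.0 and 0.912 FPKM in untreated 13, 14 and 15 and 20.1 and 30.8 FPKM with the drug. Both treated libraries held muscle transcripts, and untreated 14, which held the most, had values below both of them for 17 of the 21 members. Without untreated 14, Fosb and Klf2 passed over all genes with limma adjusted p of 0.0197 and 0.0375, and Egr1 did not (0.0577). In that fit all 28 skeletal muscle markers rose as well, so the drug and the muscle content cannot be told apart there.

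**Figure D3:**
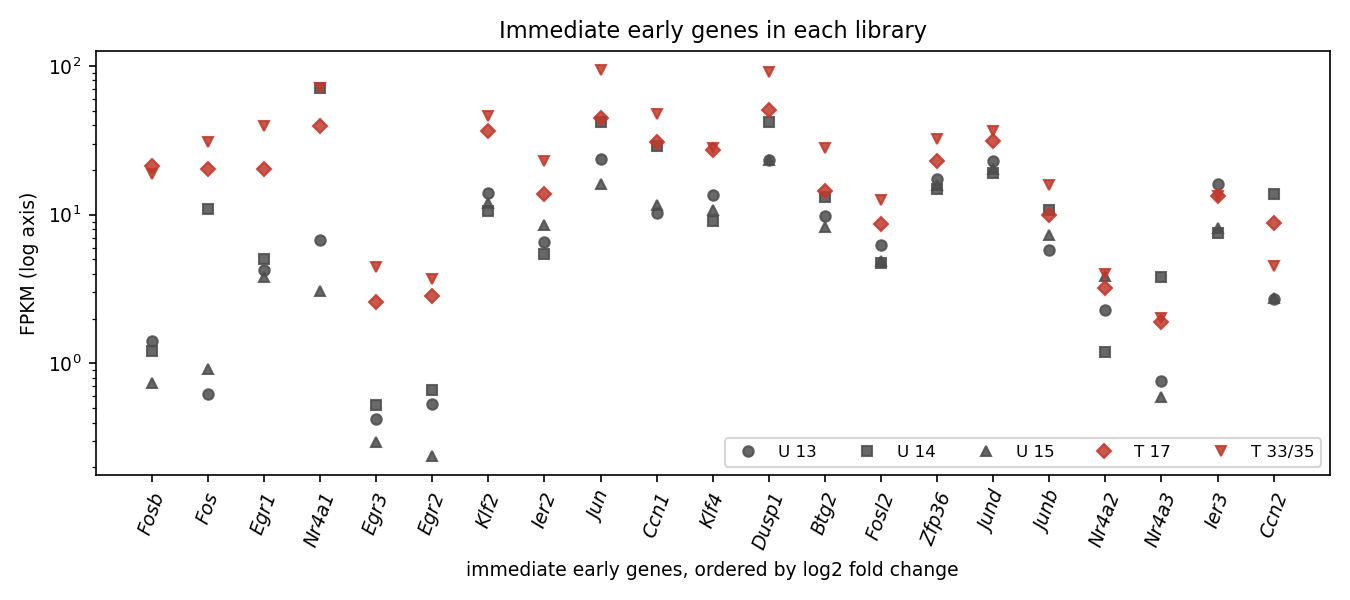
FPKM on a log axis of the 21 immediate early genes in each library (grey, untreated; red, treated), ordered by log2 fold change. Fosb, Egr1 and Klf2 are higher in both treated libraries than in all 3 untreated ones, whereas Nr4a1, Nr4a3 and Ccn2 are at least as high in untreated 14 as in treated 17.

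Further genes were separated between the groups without passing the test. Ppp1r10, a regulatory subunit of protein phosphatase 1, was measured at 8.04 ± 0.671 FPKM (SD, n = 3) without and 19.2 ± 3.56 FPKM (SD, n = 2) with the drug, and Arc, an activity-induced gene of neurons, at 0.857 ± 0.0729 and 3.14 ± 0.410 FPKM. Lower in both treated libraries were Lrrc8c, a subunit of volume-regulated anion channels, with a log2 fold change of -0.54 (SE 0.17), and Bbs5, a component of primary cilia, with -0.47 (SE 0.15). Mcf2l had -1.03 (SE 0.33). P4ha1, a collagen prolyl hydroxylase, had -1.09 (SE 0.35), and Sox18, an endothelial transcription factor, -0.69 (SE 0.23). Each of these 7 genes had a limma adjusted p of 1. Of the 13527 genes, 744 lay above and 430 below in both treated libraries relative to all untreated ones, together 8.68%, where chance gives 20%.

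Skeletal muscle markers and mast cell genes had higher means on the log2 scale in the treated group. All 28 muscle markers had higher means on the log2 scale with the drug, with a median log2 fold change of 4.19 (camera adjusted p = 3.43e-10), and the adjusted p was 0.994 with an estimated correlation. Ckm had a log2 fold change of 5.06 (SE 3.52) and Atp2a1, the calcium pump of fast muscle, 4.71 (SE 3.28), both with a limma adjusted p of 1, and their highest values were in untreated 14. On the FPKM scale 26 of the 28 markers had lower means with the drug. The means of Ckm were 912 FPKM without and 896 FPKM with it, whereas those of Atp2a1 were 1188 and 1277 FPKM. The list's median was 2.50 without untreated 15 and 7.37 without untreated 14, where all 28 markers rose. Of 7 tested neutrophil and mast cell markers, the 5 mast cell genes Cpa3, Cma1, Mcpt4, Tpsb2 and Kit had higher means with the drug and the neutrophil genes S100a8 and S100a9 lower ones. The list's median was 0.87 (camera adjusted p = 0.00579), and the adjusted p was 0.994 with an estimated correlation. Kit, the receptor for stem cell factor, was measured at 2.32 ± 0.236 FPKM (SD, n = 3) without and 3.63 ± 0.0896 FPKM (SD, n = 2) with the drug. Tpsb2, a tryptase, had a log2 fold change of 0.96 (SE 0.49, limma adjusted p = 1). No member passed the test, also when adjusted over the list alone. The list did not pass without a filter on low values (median -0.023, camera adjusted p = 0.550) or without untreated 15 (median 0.50, camera adjusted p = 0.0660). It also did not pass with sample weights (median 0.95, camera adjusted p = 0.0525). With the mean log2 and the summed FPKM muscle covariates its medians were 0.51 and 0.91 (camera adjusted p = 0.740 and 0.202). Without treated 17 its median was 0.59.

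The lists of ribosomal protein, heat shock and unfolded protein response genes had medians a little below 0 and passed camera as lower, none of them with an estimated correlation. Of 50 cytosolic ribosomal protein genes, 49 had lower means on the log2 scale with the drug, with a median log2 fold change of -0.11 (camera adjusted p = 3.61e-08, and an adjusted p of 0.994 with an estimated correlation). Rps21 and Rps28 had log2 fold changes of -0.22 (SE 0.18) and -0.17 (SE 0.18). The list's median was -0.0024 without untreated 14 (camera adjusted p = 0.761). Heat shock genes had a median of -0.14 over 14 members, 5 higher and 9 lower (camera adjusted p = 0.00551, and an adjusted p of 0.994 with an estimated correlation). Hsph1 and Hsp90ab1, 2 chaperones, had log2 fold changes of -0.93 (SE 0.41) and -0.35 (SE 0.17). Untreated 13 had the highest level of this list, and without it the median was 0.18 (camera adjusted p = 0.348); without treated 17 the camera adjusted p was 0.0809. Unfolded protein and integrated stress response genes had a median of -0.15 and a mean of 0.05 over 24 members, 9 higher and 15 lower (camera adjusted p = 0.0259, and an adjusted p of 0.994 with an estimated correlation). Atf3, a stress-induced transcription factor, had a log2 fold change of 1.32 (SE 0.59) and Sdf2l1, a factor of the endoplasmic reticulum, -0.63 (SE 0.31). That list passed without untreated 15 (median -0.17, camera adjusted p = 0.0177). It did not pass without untreated 13 (median -0.050, camera adjusted p = 0.380) or untreated 14 (median -0.18, camera adjusted p = 0.161). Its median was -0.035 without treated 17 and -0.16 without treated 33/35. With quantile normalization the ribosomal, heat shock and unfolded protein response lists did not pass (camera adjusted p = 0.155, 0.373 and 0.373). Heat shock and unfolded protein response lists also did not pass without a filter (0.130 and 0.174) or with median centring (0.104 and 0.0740). Their medians there, -0.14 and -0.15 without a filter and -0.25 and -0.26 with median centring, add no evidence. The same members were tested without a filter, and median centring shifts every gene's fold change by the same amount. The ribosomal list did not pass with sample weights (median -0.029, camera adjusted p = 0.143). With the mean log2 muscle covariate heat shock and the unfolded protein response did not pass (medians 0.0085 and -0.057, camera adjusted p = 0.285 and 0.740). The latter also did not pass with the summed FPKM covariate (median -0.14, camera adjusted p = 0.170) or centring on adipocyte identity (median -0.47, camera adjusted p = 0.311). No member of these 3 lists passed the test over all genes or adjusted over the list alone.

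In all, 6 of 13527 genes passed limma's test, 4 higher and 2 lower with the drug, against 125 at an unadjusted p under 0.05, and 0 of the 6 were annotated as protein-coding. The small nucleolar RNA genes Snord22 and Snora30 and the small RNA gene Gm24195 were listed at 0 in all untreated libraries. They measured 18.0, 13.1 and 8.26 FPKM in treated 17 and 19.4, 14.2 and 8.88 FPKM in treated 33/35. A gene with no symbol, ENSMUSG00000090407, measured 0.0266, 0.0143 and 0.0292 FPKM in the untreated libraries and 7.71 and 10.1 FPKM in the treated ones (limma adjusted p = 0.0486). Gm24332 and Gm24159, annotated as microRNA genes, were listed at 0 in both treated libraries, against 212, 138 and 107 FPKM and 212, 275 and 107 FPKM in the untreated ones. Without untreated 14 the test called 158 genes, 149 higher and 9 lower, of which 139 were protein-coding and 28 were the skeletal muscle markers. Without any other single library it called 0, with 85 to 118 genes at an unadjusted p under 0.05. The remaining 19 lists tested had medians from -0.18 (erythroid markers) to 0.25 (extracellular matrix and fibroblast genes), with camera adjusted p from 0.110 to 0.977.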

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

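The muscle covariates, protein-coding genes alone, centring on adipocyte identity and the identical tables counted separately were chosen after the results were seen. The other alternatives were planned. No paired analysis was possible because the groups share no sample numbers. Alternatives listed in advance for read counts (DESeq2 size factors, upper-quartile factors, count filters, DESeq2, voom and its quality weights) were not run because the tables hold FPKM. Read totals are unknown, so the counting error of low genes could not be given. Of 1063 values of 54 named genes and lists under the alternatives, 908 kept their direction and side of the threshold, 67 lost a call, 45 gained one and 43 changed sign. Immediate early genes kept a positive median, from 0.81 to 1.61, and passed camera in each of 20 alternatives. Their adjusted p with an estimated correlation ran from 0.178 to 0.987.

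Against 6 genes called, a pseudocount of 0.1 gave 2, no filter 0, a mean of at least 5 FPKM 1, and sample weights 10. Protein-coding genes alone gave 0, as did centring on adipocyte identity, which moved the median of all genes from 0.06 to -0.26 (median centring moved it to -0.05). The muscle covariate as a mean log2 value gave 1947 genes (1442 higher, 505 lower), and as summed FPKM 271 (263 higher, 8 lower). Single libraries left out gave 0 to 158 genes and 6 to 16 lists. Where 1 treated library was left, it was assumed to vary like the untreated ones. Against 6 lists called (3 higher, 3 lower), no filter gave 3, quantile normalization 10 (10 higher, 0 lower), sample weights 15 (3 higher, 12 lower), the mean log2 muscle covariate 11 (10 higher, 1 lower) and centring on adipocyte identity 10. Median centring gave 5 (4 higher, 1 lower). An estimated correlation and fry each gave 0.

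The changes of sign were as follows, as log2 fold changes or list medians. With sample weights the medians were -0.21 for the thermogenic programme, -0.12 for the respiratory chain, -0.19 for beta-oxidation and -0.14 for adipocyte identity. Ucp1 was then -0.55, Cox8a -0.098, Acaa2 -0.084, Acads -0.086, Cidea -0.22, Adipoq -0.20 and Dio2 -0.12. With centring on adipocyte identity, the thermogenic median was -0.086, the respiratory chain -0.24, beta-oxidation -0.081, adipocyte identity -0.15, Bace1 -0.22 and Adipoq -0.26. That centring subtracts the adipocyte list's own median in each library. The changes of sign of that list and of its member Adipoq therefore say nothing about adipocyte genes. With median centring the respiratory chain was -0.024, Bace1 -0.0084 and Adipoq -0.045. With the mean log2 muscle covariate, heat shock was 0.0085, Bace1 -0.080, Atp5g1 -0.77 and Myh7 -0.23. Myh7 is itself among the markers that form this covariate, so its change of sign is not informative. Secretases were 0.0020 without the abundant genes and 0.021 with the identical tables separate. Neutrophil and mast cell markers were -0.023 without a filter. With single libraries left out, the thermogenic median ran from -0.26 to 0.89, the respiratory chain from -0.15 to 0.23, beta-oxidation from -0.23 to 0.52, adipocyte identity from -0.16 to 0.45, secretases from -0.053 to 0.070 and heat shock from -0.36 to 0.18. Ucp1 then ran from -0.62 to 0.91, Cidea from -0.30 to 1.25, Dio2 from -0.13 to 1.78, Adipoq from -0.16 to 0.30, Cox8a from -0.18 to 0.92, Acaa2 from -0.14 to 0.82, Acads from -0.13 to 0.69 and Cebpa from -0.014 to 0.73. The cause was not tested for any of these settings. Leaving out a library shows only which library a value rests on.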

Other observations

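The splits of the libraries and the tests of explanations given here were chosen or written down after the results they measure were seen.

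Other gene groups set single libraries apart. Relative to each gene's mean over the 5 libraries, on the log2 scale, extracellular matrix and fibroblast genes had a median of -0.76 in untreated 15 and between -0.11 and 0.42 in the others. Erythroid markers had a median of 1.18 in untreated 13, against -0.61 to 0.22 in the others. The heat shock list had a median of 0.62 in untreated 13, against -0.14 to 0.03 in the others. The circadian clock list had a median of -0.39 in treated 33/35, against 0.03 to 0.33 in the others, and in that library 18 of the 21 immediate early genes were higher than in treated 17. White fat associated genes had medians of 0.31, 0.57 and -0.58 in untreated 13, 14 and 15 and -0.07 and 0.10 in the treated libraries. Their median log2 fold change between the groups was 0.05, with a mean of -0.01 and a camera adjusted p of 0.904.

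Immediate early genes had higher means in the treated libraries, with a median log2 fold change of 1.29, but untreated 13 and 15 against the 3 libraries with muscle transcripts gave -1.29, which is as large. Skeletal muscle of the kind in untreated 14 was tested by predicting each treated library as a mixture of untreated 14 and the mean of untreated 13 and 15, with the share of untreated 14 set by the muscle markers (0.412 in treated 17 and 0.151 in treated 33/35). The list lay above that prediction by a median of 0.67 in treated 17 (quartiles 0.41 and 1.57) and 1.61 in treated 33/35 (quartiles 0.97 and 2.17), which argues against such muscle as the whole cause. In 15 of the 21 members both treated values lay above all untreated ones, and any such mixture had to lie below them there. The prediction therefore largely restates that separation. Other scalings left the list's median log2 fold change at 0.97 or more, which argues against scaling. Muscle in another state, handling of the tissue before freezing, the time of day and the drug itself stay open and were not tested.

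The median of the thermogenic list was lowest in untreated 14 and intermediate in the treated libraries, though Ppargc1a and Esrrg were lowest in the treated ones. Dilution of brown fat by muscle cannot be told apart from a change in the fat itself. The median log2 ratio of untreated 14 to the mean of untreated 13 and 15 was -2.47 for 23 thermogenic genes (quartiles -3.28 and -0.85) and -1.21 for 19 adipocyte identity genes (quartiles -1.48 and -0.49), a difference of -1.26, but the quartiles overlapped and both lists hold genes that muscle also expresses. White fat in the piece cannot be told apart from brown fat of low activity, since white fat associated genes had a median 0.60 above the mean of untreated 13 and 15 (quartiles -0.30 and 1.20) but 0.16 above the higher of them, and went both ways, with Lep at 75.4 FPKM in untreated 14 against 120 and 76.9 and Agt at 6.28 FPKM against 0.777 and 0.161. A candidate explanation for the treated values is a mixture of both kinds of untreated tissue, since the thermogenic list lay 0.0368 above that mixture in treated 17 (quartiles -0.25 and 0.17) and at -0.02 in treated 33/35 (quartiles -0.33 and 0.05), and an effect of the drug stays open.

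The genes called between the groups were small RNA genes or had no symbol. Snord22, Snora30 and Gm24195 each had a ratio of treated 17 to treated 33/35 of 0.929, and the ratios differed by 0.0385%. A candidate explanation is the same small number of reads for each gene in each treated library. The estimated depths of treated 17 and treated 33/35, 1.01 and 0.960, would give a somewhat higher ratio for equal reads. Gm24159 had 2 times the value of Gm24332 in untreated 14 and the same value in untreated 13 and 15, which whole reads would also give. Of 10 splits of the libraries into 2 and 3, 2 gave as many genes, with 6 in the real split and 6 as the highest of the others, and 10 splits are too few for a share under 0.05. No biological explanation was tested for these genes.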
